A study of Mus musculus with 29 samples.

How the data were processed

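GR was profiled by ChIP-seq and ChIP-exo in livers of WT and GRdim mice at 6am, at 6pm and at 6am after prednisolone, and C/EBPβ by ChIP-seq in WT under the same conditions. Each list is 1 pool of 2 replicates per the labels. The 2 RNA polymerase II and 12 input samples that the labels also describe were not analysed here. Bowtie, HOMER and the mm9 build are named per the submitters' processing notes; their roles and versions and the threshold for calling peaks are not given in the sources used here. Positions are in mm9, counted from 1.

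The ChIP-seq files hold intervals of 200 bp sorted by a score that the authors assigned to each peak, in a unit not given in the sources used here. No score lay below 2.00, and in each list at least 99.4% of scores were whole multiples of 1 step within 0.005, as a count divided by 1 number per list would be. The step was the largest between 0.012 and 0.3 that held at least 99% of the scores. A first search over a narrower range could not have shown a ratio of steps above 1.5 and was replaced by this one after the ratio had been seen. The reciprocal of the step lay between 24.9 and 28.5 in the 9 lists. In the report the score was used only to describe, rank or filter peaks within a list, while the closing section compares the score steps of 2 lists. Scores of 1 region in several lists are given side by side without a test. A list with a fixed lowest score leaves out weaker binding, so a missing peak can be a weak one.

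The ChIP-exo files hold borders of 10 bp on 1 strand, with a deposited count of tags per border and the authors' RPM value, per the file headers. The count divided by the RPM was constant in each file and gave the size of the library. The listed borders held 1.54% to 3.27% of the tags of their library. A deposited height signal per border was present and was not used in any comparison. Other deposited values per border, a standard deviation and a number between 2 and 4 of unstated meaning, were not used either. Borders on the mitochondrial genome were listed in each file and lie in no ChIP-seq peak.

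Peaks were called shared where they overlapped by at least 1 bp, in both directions, with Wilson 95% intervals for shares and Newcombe intervals for differences of shares. These cover the counting of peaks only: peaks are not replicates, and each comparison is between 2 lists. Beside each overlap stand 100 random placements of the peaks, uniform over the span of positions listed on the same chromosome. They set a floor and are not a model of open chromatin. New peaks are those listed after prednisolone and not at 6am, lost peaks the reverse, and kept peaks those listed in both. For gains and losses of C/EBPβ at the same GR peaks, the interval is that of a paired difference.

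For ChIP-exo, the border with the most tags on each strand within 100 bp of the centre of a ChIP-seq peak was taken, and the distance is the position of the minus-strand border less that of the plus-strand border, between centres of the 10 bp features. The share per 3 bp between 40 and 60 bp served as background. At regions of both genotypes the borders of both libraries were taken around the centre of the WT peak, which can differ from that of the GRdim peak. The interval there treats the 2 libraries as independent sets.

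The rule for named regions was fixed before the data were examined: for each pair of lists the highest-scoring peaks present in 1 list and absent from the other, and the highest-scoring shared ones, 3 of each where no annotation of the build is used. The overlaps, the C/EBPβ shares per condition and the ChIP-exo support were also fixed before the data were examined. The groups of new, kept and lost peaks and the border distances were added afterwards. Alternatives were centres within 100 bp, the higher-scoring 50% of each list and lists of equal length. Those added afterwards were peaks with borders of both strands, borders within 60 bp, the closest opposite borders and at least 20 tags on each border.

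Shares of peaks with 10 sequence motifs and of 11 gene lists near peaks were planned. They need the mm9 sequence and annotation, which were not used here, so regions are given by position with no gene name and no statement of exon or intron.

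The code was tested on simulated data. Simulated shares of 20%, 50% and 80% of 4000 peaks came out as 20%, 50.1% and 80.0%, a simulated 30% of 2000 peaks with borders 29 to 31 bp apart came out as 30%, and the interval of a difference covered the simulated value in 94.4% of 1000 draws. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.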

Results

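Binding of the glucocorticoid receptor (GR), the nuclear receptor for corticosterone and for synthetic glucocorticoids, was profiled in mouse liver by ChIP-seq and by ChIP-exo, in which an exonuclease trims the precipitated DNA to the edge of the bound protein. The animals were wild type (WT) or carried GRdim, a receptor mutation known to impair dimerization of GR. They were males of 12 weeks on a 12 h light cycle, and livers were taken at 6am, at the start of the light phase, or at 6pm, at the start of the dark phase. A further set was taken at 6am after 24 h with subcutaneous pellets of prednisolone, a synthetic glucocorticoid, at 12 mg/kg. C/EBPβ, a transcription factor abundant in liver, was profiled by ChIP-seq in WT under the same 3 conditions. Each of the 9 ChIP-seq lists and 6 ChIP-exo lists came from 2 pooled replicates, so every condition was 1 measurement with no spread between replicates, and no p-value is given. The 95% intervals below cover only the counting of peaks, and the comparisons are between lists.

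The GR lists held 5781 peaks in WT at 6am, 14270 at 6pm and 4304 after prednisolone. In GRdim they held 3183, 7440 and 3208 peaks. The C/EBPβ lists were longer, with 21644, 26226 and 21941 peaks. Every ChIP-seq peak was 200 bp wide. The ChIP-exo lists held 66573, 54636 and 49189 borders of 10 bp in WT and 14391, 35658 and 35220 in GRdim. Their libraries, from the tags and their RPM, were 55.7, 43.1 and 54.7 M tags in WT and 31.6, 43.8 and 45.2 M tags in GRdim. The depth of the ChIP-seq libraries is not given in the sources used here.

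Between 6am and 6pm, the start of the light and dark phases, the GR ChIP-seq lists grew in both genotypes. The 6pm list was 2.47 times as long as the 6am list in WT and 2.34 times in GRdim, while the C/EBPβ list of 6pm was 1.21 times as long. Nearly all regions of 6am were listed again: 97.5% of the WT 6am peaks (95% interval 97.1 to 97.9) were found at 6pm, and 92.9% (92.0 to 93.8) of the GRdim 6am peaks. In the other direction, 39.5% (38.7 to 40.3) of the WT 6pm peaks and 39.8% (38.7 to 40.9) of the GRdim 6pm peaks were found at 6am. The 8633 WT peaks of 6pm that the 6am list lacked had a median score of 2.70, against 5.30 for the 5637 listed at both times. Of those 8633 peaks, 56.5% (55.5 to 57.6) nevertheless held a ChIP-exo border of the 6am library. A border of the 6pm library was found at 65.1% (64.0 to 66.1) of them. The WT ChIP-exo list did not grow, and was 0.821 times as long at 6pm as at 6am.

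Among the regions at both times, the highest-scoring in WT at 6am lay on mm9 chromosome 2 at 167670160 to 167670359, on chromosome 7 at 71041868 to 71042067 and on chromosome 4 at 150059298 to 150059497. Their scores were 23.56, 23.41 and 22.95 at 6am and 25.47, 26.16 and 26.35 in the 6pm list. The highest-scoring 6pm peaks without a 6am peak lay on chromosome 4 at 150123306 to 150123505, chromosome 15 at 31183860 to 31184059 and chromosome 2 at 27451882 to 27452081, with scores of 9.24, 8.40 and 8.22. The nearest 6am centres were 226, 1104 and 760 bp away. The highest-scoring 6am peaks without a 6pm peak lay on chromosome 16 at 26706150 to 26706349, chromosome 3 at 82824226 to 82824425 and chromosome 16 at 13358547 to 13358746. Each of those 3 had a 6pm peak centred 209 to 330 bp away. Shares were taken at 1 bp of overlap, and 100 random placements of the WT 6am peaks met the 6pm list at up to 0.467%. With lists of equal length, 78.6% of WT peaks and 70.8% of GRdim peaks were shared between the 2 times in either direction.

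Prednisolone was compared with untreated 6am livers to follow GR binding under an added agonist. In WT, 3193 GR regions were listed in both states, 2588 of the 6am peaks were lost and 1111 peaks were new. Thus 55.2% (53.9 to 56.5) of the 6am peaks were found after prednisolone, and 74.2% (72.9 to 75.5) of the prednisolone peaks at 6am. The WT list was 0.745 times as long after treatment, but among peaks scoring at least 4 the new ones were more frequent than the lost ones. Of 1198 such prednisolone peaks, 13.7% (11.9 to 15.8) were absent at 6am, and of 1439 such 6am peaks, 5.77% (4.68 to 7.09) were absent after prednisolone. These shares also depend on the length of the list that was searched and on the rank of a score of 4 in each list.

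The highest-scoring new peaks in WT lay on chromosome 17 at 56432415 to 56432614, on chromosome 16 at 93913136 to 93913335 and on chromosome 11 at 83211222 to 83211421, with scores of 15.09, 12.87 and 12.12. None of the 3 GRdim lists held any of them, and the nearest WT 6am peaks were 73078, 52803 and 164822 bp away. The chromosome 17 region was listed in WT at 6pm with a score of 2.05, and both it and the chromosome 11 region held a C/EBPβ peak after prednisolone and at neither untreated time. Of the 1111 new peaks, 664 (59.8%, 56.9 to 62.6) were in the WT 6pm list and 447 were not. The highest-scoring lost peaks lay on chromosome 2 at 31320217 to 31320416, chromosome 4 at 34830316 to 34830515 and chromosome 10 at 127396308 to 127396507, with 6am scores of 6.97, 6.51 and 6.39. The chromosome 2 peak had a prednisolone peak centred 283 bp away, and the other 2 remained listed in GRdim after prednisolone. The 3 peaks on chromosomes 2, 7 and 4 that led the 6am list scored 25.41, 25.41 and 20.42 after prednisolone.

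In GRdim, 2063 of the 3183 peaks of 6am were found after prednisolone (64.8%, 63.1 to 66.5), 1120 were lost and 1145 were new. The share found was 9.58 percentage points lower in WT than in GRdim (Newcombe interval of WT minus GRdim -11.7 to -7.47). This difference was absent with lists of equal length within each genotype, where it turned to 1.53 points (-0.645 to 3.72), and with equal lengths in both genotypes (0.503 points, -1.84 to 2.85). Many peaks missing from a list held ChIP-exo borders in that state: 60.7% (57.8 to 63.5) of the new WT peaks in the 6am library and 65.8% (64.0 to 67.6) of the lost ones in the prednisolone library. Of the 447 new peaks that the 6pm list lacked as well, 179 held a 6am border and 268 did not. Random placements of these groups held a border in at most 1.12% of cases.

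**Figure D1:**
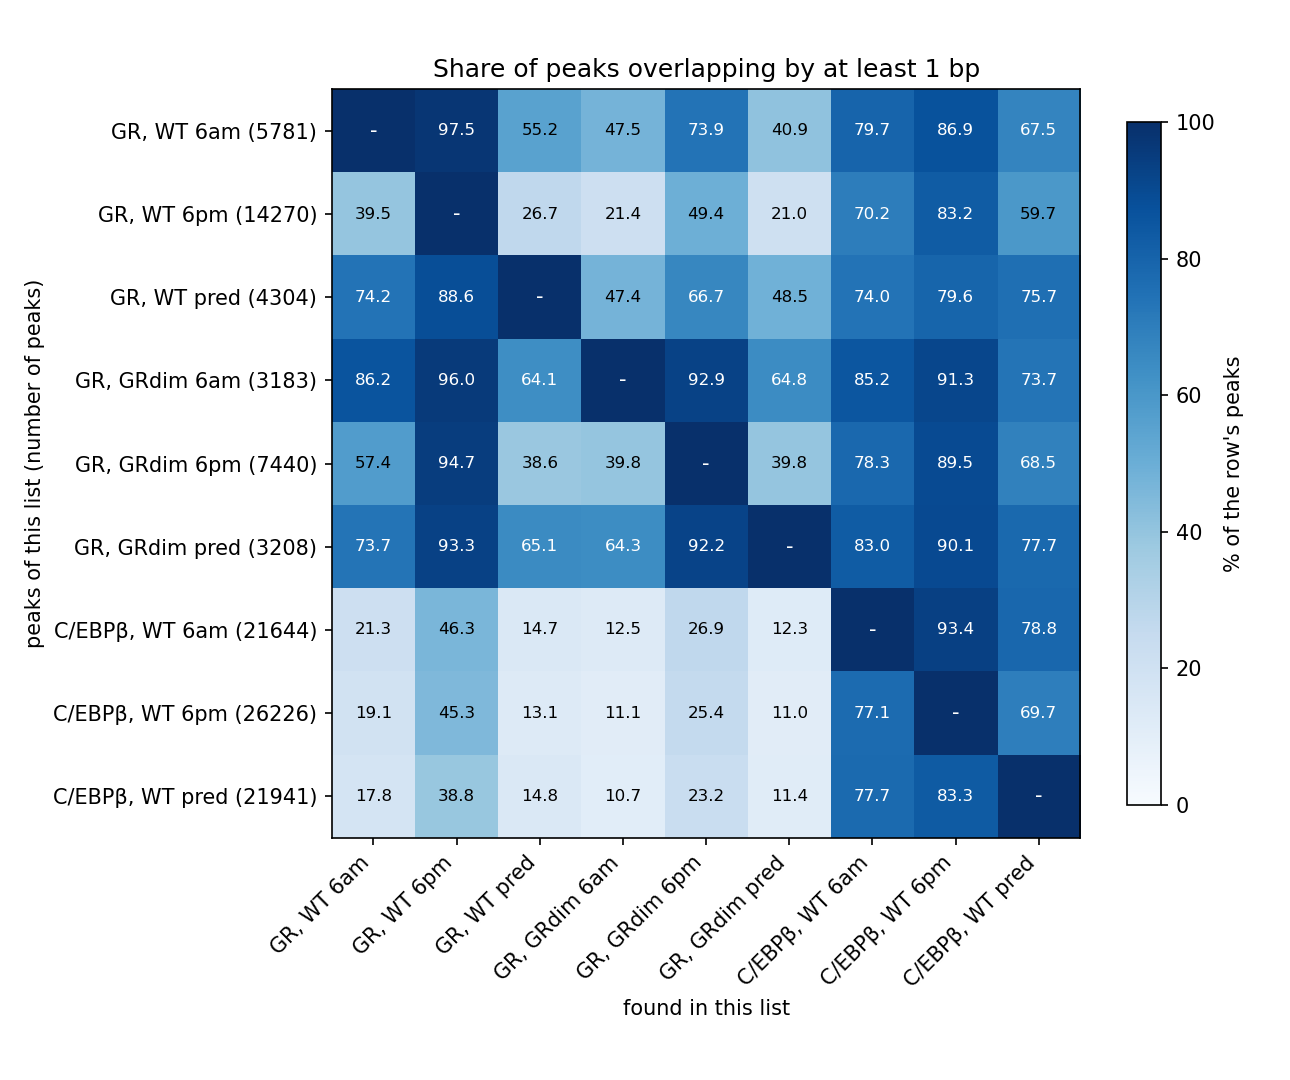
Share of the peaks of each list (rows, with the number of peaks) that overlapped a peak of another list (columns) by at least 1 bp, in percent of the row's peaks; pred stands for prednisolone at 6am. Of the GR peaks of WT at 6am 97.5% were found at 6pm and 55.2% after prednisolone, and C/EBPβ peaks met GR peaks less often than GR peaks met C/EBPβ peaks.

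WT and GRdim were compared under each condition to ask where the mutant receptor was found. In the lists as deposited, 47.5% (46.2 to 48.8) of the WT peaks were listed in GRdim at 6am, 49.4% (48.5 to 50.2) at 6pm and 48.5% (47.0 to 50.0) after prednisolone. Of the GRdim peaks, 86.2% (85.0 to 87.4), 94.7% (94.1 to 95.2) and 65.1% (63.4 to 66.7) were found in the longer WT lists. With lists of equal length the shares were 63.3%, 74.8% and 52.0% in either direction, and in the higher-scoring 50% of each list 44.7%, 47.6% and 40.2% of WT peaks were found in GRdim. Overlapping GR peaks merged into 15329 regions, of which 7412 were listed in both genotypes, 7444 in WT alone and 473 in GRdim alone. Of the regions in WT alone, 5386 were in the WT 6pm list, the longest, and in no other list. All 6 lists shared 1545 regions, and 546 regions were in all 3 WT lists and in no GRdim list.

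Among peaks with scores of at least 4, those of WT were more often absent from GRdim than those of GRdim from WT, in lists that differ in length and in the rank of that score. Of WT peaks scoring at least 4, 29.6% (27.3 to 32.0) at 6am, 17.5% (16.5 to 18.6) at 6pm and 47.7% (44.8 to 50.5) after prednisolone were absent from GRdim. Of GRdim peaks scoring at least 4, 1.13% (0.518 to 2.44), 0.777% (0.455 to 1.32) and 3.94% (2.36 to 6.51) of 355 were absent from WT. The highest-scoring WT peaks absent from GRdim at 6am lay on chromosome 5 at 121784129 to 121784328, chromosome 6 at 72111099 to 72111298 and chromosome 2 at 167686130 to 167686329, with scores of 18.08, 16.25 and 15.49. All 3 were in the GRdim 6pm list, where their scores were 4.85, 3.79 and 2.21. At 6pm the highest-scoring WT peaks absent from GRdim were on chromosome 17 at 28557179 to 28557378, chromosome 19 at 5850164 to 5850363 and chromosome 17 at 81784937 to 81785136, with scores of 17.17, 16.00 and 15.71, and the chromosome 19 peak had a GRdim peak centred 226 bp away. After prednisolone, the regions on chromosomes 5 and 2 named at 6am had the highest scores of those absent from GRdim, 18.35 and 17.71, followed by chromosome 10 at 59432568 to 59432767 with 16.17, which no GRdim list held.

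In the opposite direction, the region on chromosome 10 at 7494139 to 7494338 was listed in GRdim after prednisolone with a score of 7.51 and at 6pm with 7.45, and in no WT list. The region on chromosome 3 at 9822077 to 9822276 scored 7.84 in GRdim after prednisolone and 4.95 at 6pm and was likewise in no WT list. The region on chromosome 7 at 46458377 to 46458576, with 6.84 in GRdim after prednisolone, was in the WT lists of 6am and 6pm with 6.39 and 8.88. The WT peaks on chromosomes 2 and 7 with the highest scores were in every GR list of both genotypes. Within GRdim the chromosome 2 region scored 3.91 at 6am, 14.89 at 6pm and 7.32 after prednisolone.

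The peaks that were new in WT after prednisolone were found in GRdim less often than those also listed at 6am. Of the new peaks, 22.1% (19.8 to 24.7) were in the GRdim prednisolone list, and of the kept peaks 57.7% (55.9 to 59.4), a difference of -35.5 percentage points (-38.4 to -32.5). The difference widened with the score, from -22.4 points in the lowest-scoring of 5 equal parts of the WT list to -50.2 points in the highest, where 6.90% of 116 new and 57.0% of 745 kept peaks were found. GRdim peaks showed a difference in the same direction, since 40.4% (37.6 to 43.3) of its new and 78.7% (76.9 to 80.4) of its kept peaks were in the WT prednisolone list. The 6pm list likewise: WT peaks of 6pm that 6am lacked were in GRdim at 6pm in 32.3% (31.3 to 33.3) of cases, and those of both times in 75.5% (74.3 to 76.6). That difference of -43.2 points was -16.6 points (-19.6 to -13.6) with lists of equal length.

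**Figure D2:**
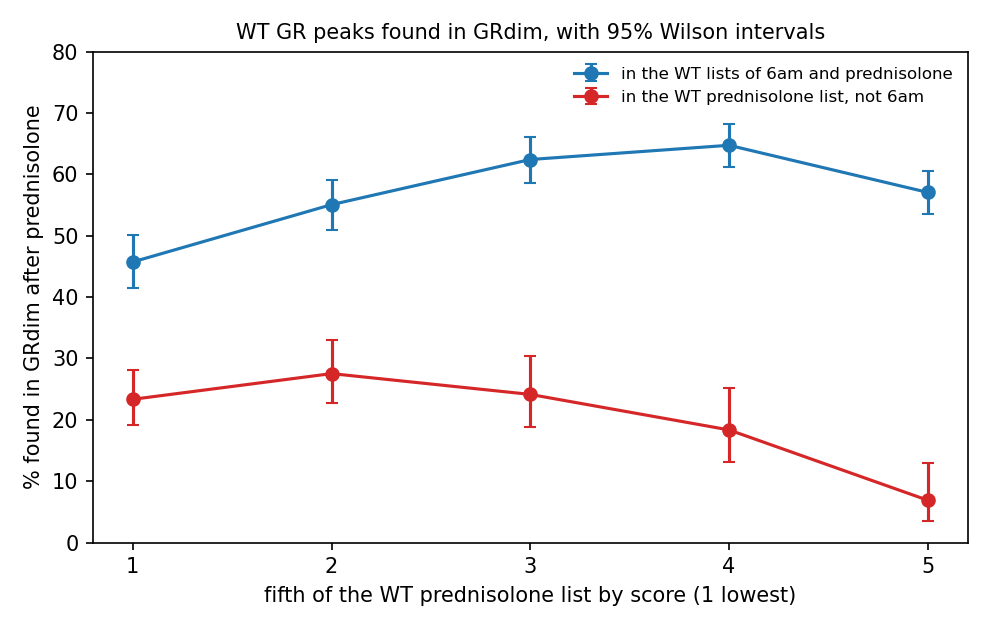
Share of WT prednisolone GR peaks found in the GRdim prednisolone list (vertical axis, percent) by part of the WT list in order of score, 5 equal parts (horizontal axis), for peaks also listed in WT at 6am and for peaks not listed there; bars are 95% Wilson intervals. In the highest-scoring part 57.0% of the kept and 6.90% of the new peaks were found.

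Of WT peaks missing from the GRdim list, 26.4% (24.8 to 27.9) at 6am, 26.7% (25.7 to 27.7) at 6pm and 41.8% (39.7 to 43.8) after prednisolone held a ChIP-exo border of the GRdim library of that condition. The WT library marked 95.9%, 64.6% and 92.8% of the same peaks. The GRdim libraries marked 77.6%, 82.2% and 97.1% of the GRdim peaks, so shares found in them also depend on the library. The WT lists were 1.82, 1.92 and 1.34 times as long as those of GRdim.

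C/EBPβ peaks were found at most GR peaks of WT. Of the C/EBPβ peaks of 6am, 93.4% (93.1 to 93.7) were found at 6pm and 78.8% (78.2 to 79.3) after prednisolone. The highest-scoring C/EBPβ peaks new after prednisolone lay on chromosome 7 at 147818977 to 147819176, chromosome 1 at 82199352 to 82199551 and chromosome 3 at 137769979 to 137770178, with scores of 11.56, 10.95 and 10.95. The first of these also held GR peaks in WT at 6pm and after prednisolone, the second a GR peak after prednisolone and the third no GR peak in any list. The highest-scoring lost C/EBPβ peaks lay on chromosome 3 at 116653776 to 116653975, chromosome 11 at 35776958 to 35777157 and chromosome 12 at 105227328 to 105227527, and each had a C/EBPβ peak after prednisolone centred 208 to 261 bp away.

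A C/EBPβ peak of the same condition overlapped 79.7% (78.7 to 80.7) of the WT GR peaks at 6am, 83.2% (82.6 to 83.8) at 6pm and 75.7% (74.3 to 76.9) after prednisolone, with at most 0.697% in random placements. The share was 4.06 points lower after prednisolone than at 6am (prednisolone minus 6am -4.06, Newcombe interval -5.71 to -2.42) and 3.49 points higher at 6pm (2.30 to 4.71). At equal list lengths these differences were -6.74 and 8.25 points, and at 6pm they were 6.08 points with centres within 100 bp and 7.70 points in the higher-scoring 50% of each list.

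At GR peaks that were new or lost after prednisolone, C/EBPβ listings changed in the same direction, while most changes of the C/EBPβ list lay away from listed GR peaks. Of the 4886 C/EBPβ peaks new after prednisolone, 6.92% (6.24 to 7.66) overlapped a GR peak of that condition, against 14.8% of all C/EBPβ peaks after prednisolone, and of the 4589 lost ones 17.9% (16.8 to 19.0) overlapped a 6am GR peak, against 21.3% of all at 6am. At the 1111 GR peaks new after prednisolone, the share with a C/EBPβ peak went from 45.9% in the 6am C/EBPβ list to 66.2% in the prednisolone list, with 245 peaks gaining a C/EBPβ peak and 19 losing one. At the 447 new peaks that the 6pm GR list lacked too, it went from 17.4% to 46.8%, with 135 gains and 4 losses. At the 2588 lost GR peaks it went from 74.5% to 53.5%, with 27 gains and 569 losses, and at the 3193 kept peaks from 83.8% to 78.9%. Of the GR peaks with a C/EBPβ overlap at 6am, 29.5% (27.5 to 31.6) of the 1927 lost and 9.27% (8.23 to 10.4) of the 2676 kept had none after prednisolone. At the 8633 GR peaks of 6pm that 6am lacked, the share went from 63.3% at 6am to 79.9% at 6pm, with 1503 gains and 68 losses, and at the 5637 GR peaks of both times from 80.8% to 88.3%, with 477 gains and 57 losses. Of GR peaks without a C/EBPβ peak at 6am, 47.4% (45.6 to 49.1) of the former and 44.2% (41.2 to 47.1) of the latter held one at 6pm, so the gain at 6pm was similar at GR peaks of either group. These groups of GR peaks, unlike the shares per condition, were chosen after the data were seen.

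**Figure D3:**
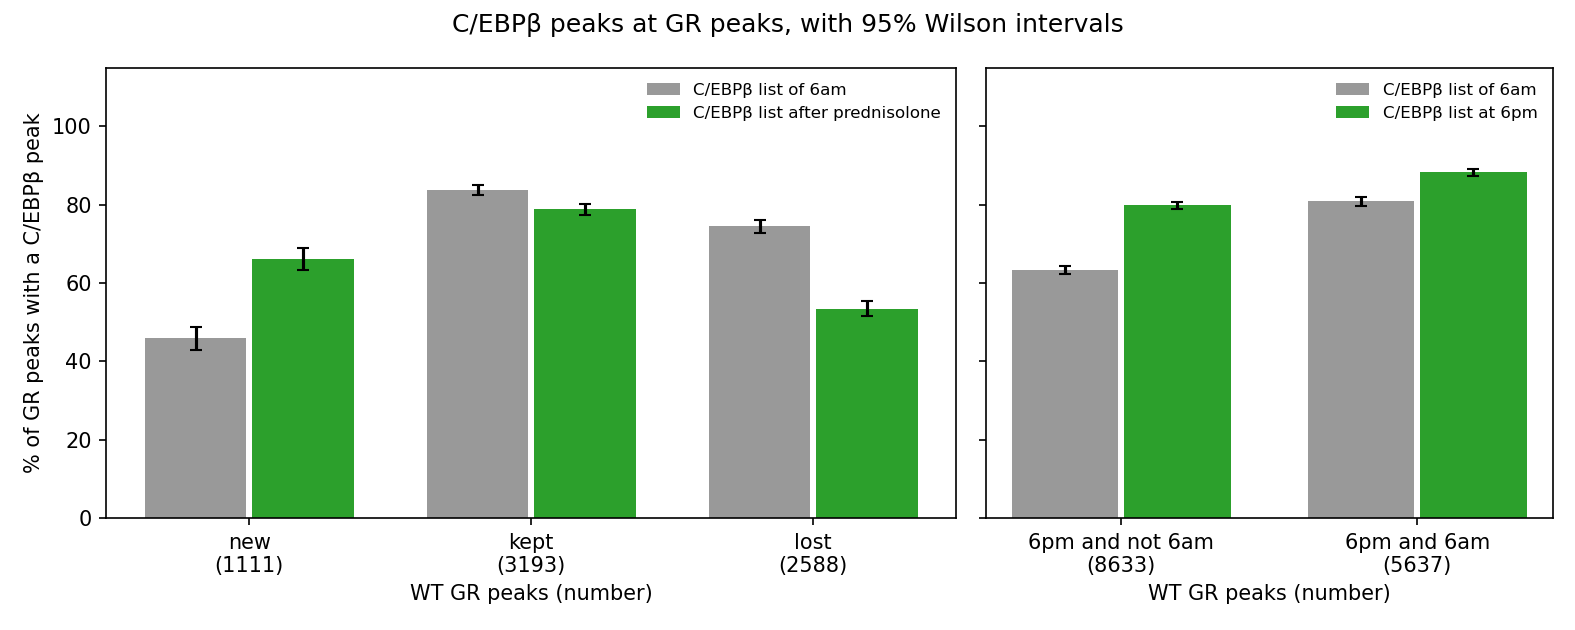
Percent of WT GR peaks that overlap a C/EBPβ peak (vertical axis) in the C/EBPβ list of 6am (grey) and in that of prednisolone or 6pm (green), for groups of GR peaks (horizontal axis, number of peaks in parentheses); bars carry 95% Wilson intervals. The share rises from 45.9% to 66.2% at new GR peaks and falls from 74.5% to 53.5% at lost ones.

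C/EBPβ was also less frequent at GR peaks listed in WT alone than at those listed in both genotypes. At 6am 71.4% (69.8 to 73.0) of WT-only and 88.9% (87.6 to 90.0) of shared GR peaks held a C/EBPβ peak, at 6pm 74.7% (73.7 to 75.7) and 91.9% (91.2 to 92.5), and after prednisolone 65.0% (62.9 to 66.9) and 87.0% (85.5 to 88.4). The differences were -17.4 (-19.4 to -15.4), -17.2 (-18.3 to -16.0) and -22.1 points (-24.5 to -19.6). WT-only peaks also had lower scores, with medians of 2.55, 2.63 and 2.78 against 3.46, 4.57 and 3.08.

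ChIP-exo borders marked most GR peaks. Over the 6 conditions together, 84.9% (84.6 to 85.3) of ChIP-seq peaks held a border of the same condition. In WT the share was 97.6% (97.2 to 98.0) at 6am, 77.0% (76.3 to 77.6) at 6pm and 95.3% (94.6 to 95.9) after prednisolone, and in GRdim 77.6% (76.1 to 79.0), 82.2% (81.3 to 83.1) and 97.1% (96.4 to 97.6). At 6pm in WT, peaks also listed at 6am held a border in 95.2% (94.6 to 95.7) of cases and the others in 65.1% (64.0 to 66.1). Random placements met a border in at most 0.381% of cases.

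The distance from the strongest plus-strand border to the strongest minus-strand border of a peak differed between the genotypes. In WT the commonest distance above 15 bp was 30 bp under all 3 conditions, and in GRdim it was 25 bp at 6am and after prednisolone and 24 bp at 6pm. Both genotypes had a further mode at 11 or 12 bp, and borders 10 to 12 bp apart were more frequent in WT, at 10.3%, 5.38% and 13.6% of peaks at 6am, at 6pm and after prednisolone, than in GRdim, at 5.80%, 3.39% and 5.52%. Borders 29 to 31 bp apart marked 9.12% (8.35 to 9.95) of the 4966 WT peaks with both borders at 6am, 6.17% (5.61 to 6.78) of 6482 at 6pm and 13.1% (12.0 to 14.2) of 3406 after prednisolone. In GRdim the shares were 2.39% (1.71 to 3.34) of 1380, 2.31% (1.89 to 2.83) of 3891 and 2.24% (1.74 to 2.88) of 2590, close to the 2.39%, 2.62% and 2.53% that 3 bp held on average between 40 and 60 bp. Borders 24 to 26 bp apart were less frequent in WT, at 3.44% (2.87 to 4.10), than in GRdim, at 6.10% (5.24 to 7.09), after prednisolone. The WT share was still above its background of 1.98%.

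**Figure D4:**
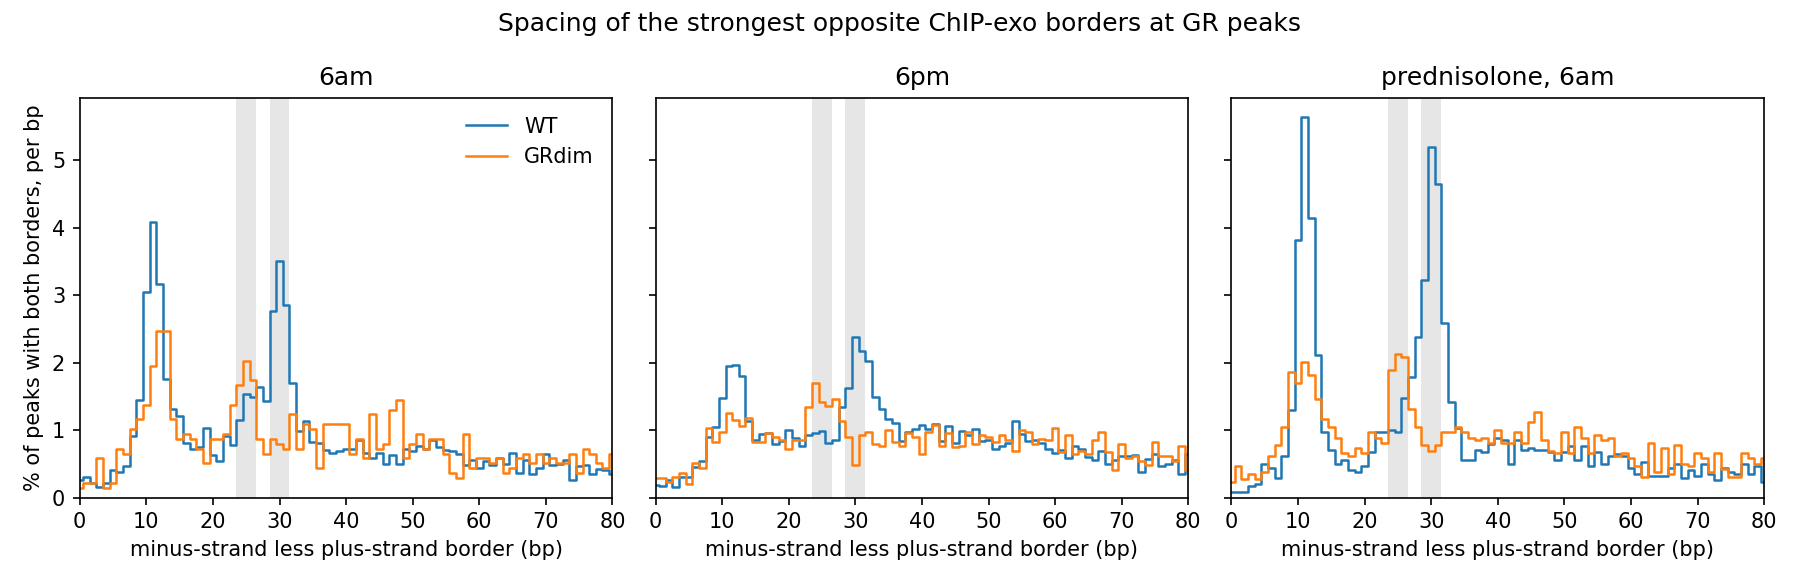
Distance from the strongest plus-strand to the strongest minus-strand ChIP-exo border within 100 bp of the centre of each GR peak (horizontal axis, bp), in percent of the peaks with both borders (vertical axis), for WT (blue) and GRdim (orange) under each condition; grey bands mark 24 to 26 and 29 to 31 bp. WT shows a mode at 30 bp under every condition, and GRdim one at 24 or 25 bp.

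The 29 to 31 bp difference remained at the same regions but was smaller there. Over all peaks it was 6.73 points at 6am, 3.86 at 6pm and 10.8 after prednisolone. Among regions listed in both genotypes after prednisolone, 1543 had both borders in each library around the centre of the WT peak. There 6.87% in WT and 2.46% in GRdim had borders 29 to 31 bp apart, a difference of 4.41 points (2.94 to 5.93). For 24 to 26 bp the shares were 4.21% and 6.87%, a difference of -2.66 points (-4.29 to -1.05). The 29 to 31 bp difference was 4.66 points (3.04 to 6.35) at 6am and 2.86 points (1.87 to 3.87) at 6pm, and the 24 to 26 bp difference -0.395 (-2.16 to 1.37) and -1.76 points (-2.72 to -0.810). For 10 to 12 bp the difference was 4.10, 1.14 and 3.37 points at 6am, at 6pm and after prednisolone, with intervals above 0. The windows were chosen after the distances were seen. With the closest pair of opposite borders in place of the strongest, a measure that favours short distances by construction, the 29 to 31 and 24 to 26 bp differences were -0.208 (-1.16 to 0.728) and 0.208 points (-1.24 to 1.66). With at least 20 tags on each border the 24 to 26 bp difference was -2.34 points, with an interval that included 0 (-6.78 to 2.04).

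Within the WT libraries, the 29 to 31 bp distance was more frequent at peaks listed in WT alone than at peaks of both genotypes. The shares, of peaks with both borders, were 11.9% and 6.55% at 6am, 8.66% and 5.09% at 6pm and 19.8% and 6.70% after prednisolone, with differences of 5.33 (3.72 to 6.95), 3.57 (2.22 to 5.03) and 13.1 points (10.8 to 15.3). At 6pm only 1963 of 7227 WT-only peaks had both borders, against 4519 of 7043 peaks of both genotypes. Peaks lost after prednisolone showed it less often in the 6am library than kept peaks, at 4.58% against 12.1% (difference -7.50 points, -8.98 to -5.99). Both borders were present at 1963 of 2588 lost and 3003 of 3193 kept peaks, whose median 6am scores were 2.47 and 3.65. New peaks showed the 29 to 31 bp distance more often in the prednisolone library than kept peaks, at 16.1% against 12.1% (4.01 points, 1.32 to 6.93).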

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

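The ChIP-exo lists changed in length in opposite directions in the 2 genotypes, and the ChIP-seq list shortened after prednisolone in WT alone; none of these differences was tested, since each list was 1 pool. After prednisolone the ChIP-seq list was 0.745 times as long as at 6am in WT (4304 against 5781 peaks) and 1.01 times in GRdim (3208 against 3183 peaks), which is nearly equal. The ChIP-exo list was 0.739 times as long after prednisolone as at 6am in WT and 2.45 times in GRdim. At 6pm the ChIP-exo list was 0.821 times as long as at 6am in WT and 2.48 times in GRdim. The GRdim 6am ChIP-exo list, which enters both of the GRdim ratios, was the shortest, with 14391 borders from 31.6 M tags, the smallest of the 6 libraries.

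Borders on the mitochondrial genome, which count in these list lengths and entered no comparison of peaks, took a large part of the listed ChIP-exo tags. Their share was 28.6% in WT at 6am, 5.21% at 6pm and 30.5% after prednisolone, and in GRdim 74.6%, 28.9% and 54.2%. Between 838 and 872 borders carried these tags in each list. In GRdim the share was higher than in WT under each of the 3 conditions, with 1 pool per condition and no test.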

How the results depend on the processing

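Of the 55 alternative values for the main results, 26 stayed within the interval of the value reported, 25 left it and 4 changed sign; where no cause is named, the cause was not tested. With centres within 100 bp, the share found at 6pm was 96.5% for WT 6am GR peaks, 91.6% for GRdim and 92.7% for C/EBPβ, and the C/EBPβ share at GR peaks differed by 6.08 points between 6pm and 6am. In the higher-scoring 50% of each list, 96.4% of WT 6am peaks were found at 6pm and 53.0% after prednisolone. The shares of WT peaks found in GRdim were 44.7% at 6am, 47.6% at 6pm and 40.2% after prednisolone. The GRdim 6am peaks were found at 6pm in 90.5% and after prednisolone in 62.8% of cases, C/EBPβ 6am peaks at 6pm in 92.7%, and ChIP-exo borders at 84.0% of GR peaks. There the 6pm minus 6am difference in C/EBPβ share was 7.70 points, and that at lost GR peaks after prednisolone -16.6 points. With lists of equal length, by construction of shorter lists, 78.6% of WT peaks were shared between 6am and 6pm and 66.0% between 6am and prednisolone. WT peaks were found in GRdim in 63.3%, 74.8% and 52.0% of cases at 6am, at 6pm and after prednisolone, GRdim peaks of 6am at 6pm in 70.8% and C/EBPβ peaks in 86.4%. The C/EBPβ differences were -6.74 and 8.25 points. Among WT peaks with borders of both strands, chosen after seeing the data, new minus kept peaks in GRdim differed by -40.9 points. With the closest opposite borders, also added later and by construction short, the genotype difference at 29 to 31 bp turned to -0.208 and at 24 to 26 bp to 0.208 points, with intervals that included 0. The difference between WT and GRdim in 6am peaks found after prednisolone, with alternatives added after seeing the data, turned to 1.53 points with lists of equal length within each genotype and to 0.503 points with equal lengths in both. The other differences that were run kept their sign. Of the 63 alternative values for the remaining results, 27 stayed within the interval and 36 did not. Leaving out a replicate was not possible in pooled lists. Equal lengths were not run for the ChIP-exo lists, and the motif and gene list alternatives were not run, as no mm9 sequence or annotation was used. No paired analysis was possible because the lists pool their replicates and only the input samples, which were not analysed here, carry replicate numbers. The lowest score of each list and 1 pool per condition limit all of these results.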

Other observations

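Of the 1145 peaks new in GRdim after prednisolone, 80.3% (77.9 to 82.5) were in the GRdim 6pm list and 85.1% (82.9 to 87.0) in the WT 6pm list, lower than the 92.2% and 93.3% of all GRdim prednisolone peaks. Of the 1111 peaks new in WT, 59.8% were in the WT 6pm list. C/EBPβ also differed between these groups. The WT 6am C/EBPβ list held 70.0% (67.2 to 72.5) of the new GRdim peaks and 45.9% (43.0 to 48.8) of the new WT peaks. Of GRdim peaks missing from the WT list of the same condition, 84.7% (81.0 to 87.8) at 6am, 38.3% (33.6 to 43.2) at 6pm and 72.1% (69.4 to 74.6) after prednisolone held a ChIP-exo border of the WT library.

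The tests of library depth and of the same regions below, and the comparison by rank, were chosen after their results, or most of what they measure, were seen: the distances in WT at regions of both genotypes and in GRdim over all its peaks were known by then. The score-weighted test and those on borders of both strands and on 20 tags were set out before their results were seen, on patterns found in the same data.

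WT peaks new after prednisolone were found in GRdim less often than kept peaks. Weaker peaks missed in the shorter GRdim list were predicted to leave at most 10 points once weighted to 1 score distribution. The difference was -32.9 points (-36.0 to -29.8), so the score in the WT prednisolone list, in 5 parts, did not account for it. Kept peaks were called in 2 WT lists and new peaks in 1, so equal scores need not mean equal strength in GRdim, and weaker peaks are not excluded. Spurious peaks in the WT list were predicted not to carry borders of both strands, and among WT peaks that did the difference was -40.9 points (-44.1 to -37.4). That premise was not tested, and 60.7% of new WT peaks held a border even in the 6am library. A hypothesis is that part of the binding gained with prednisolone may need the dimerization that GRdim impairs, but new GRdim peaks were also found less often in WT, by -38.3 points (-41.6 to -34.9). A gap was present within WT too, where 59.8% of the new and 98.7% of the kept peaks were in the WT 6pm list. For a comparison by rank all 4 lists were cut to 3183 peaks. This shortened the WT 6am list from 5781 peaks and left the GRdim 6am list whole. WT peaks called new in that comparison can therefore be listed at 6am in the full list. With these equal lengths, in the highest-ranked of 5 parts of each list 6.90% (3.54 to 13.0) of 116 new WT peaks were in GRdim. Of 54 new GRdim peaks there, 61.1% (47.8 to 73.0) were in WT. In the 2 lowest-ranked parts the order was the reverse, with 36.4% and 39.7% of new WT peaks against 19.1% and 25.6% of new GRdim peaks. Kept peaks had the same order, with 60.7% (WT) against 93.3% (GRdim) in the highest part and 60.5% against 37.9% in the lowest. The reversal was thus not particular to new peaks. With the uncut lists, 23.3% and 27.5% of new WT peaks in the 2 lowest of 5 parts were in GRdim. At equal lengths and in percentage points, new minus kept was more negative for WT peaks in all 5 parts. It was -53.8 (-59.1 to -46.3) against -32.2 points (-45.6 to -20.1) in the highest part. In the lowest it was -24.1 (-31.5 to -16.3) against -18.9 points (-26.2 to -11.6), with overlapping intervals. The intervals also overlapped in parts 2 and 4, counted from the lowest. Kept shares differed between the genotypes in each part, so the order may not hold on a relative scale, which was not examined. The hypothesis and differences between the pooled animals stay open.

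The 29 to 31 bp distance of opposite borders was more frequent in WT than in GRdim after prednisolone. Different regions in the 2 lists were not the whole cause, since a difference of 4.41 points (2.94 to 5.93) remained at the same regions. It was smaller than the 10.8 points (9.56 to 12.1) over all peaks, so different regions may carry part of the pattern. At the 299 of the same regions with at least 20 tags on each border the difference was 4.35 points (0.883 to 8.06). Borders under 20 tags were thus not the whole cause. The filter set a lowest count and did not match the counts of the 2 libraries, so fewer tags per border in GRdim were not excluded. A candidate explanation is a different arrangement of the receptor on DNA in the 2 genotypes, which may leave borders 30 bp apart more often in WT and 24 or 25 bp apart more often in GRdim. The 24 to 26 bp distance was not particular to GRdim. In WT it marked 4.17% of peaks at 6am and 3.44% after prednisolone, each against a background of 1.98%, but 2.75% against 2.68% at 6pm. Borders 10 to 12 bp apart were also more frequent in WT at the same regions, so the difference is not confined to 1 distance, and without the mm9 sequence the motif under each border was not examined. A difference in exonuclease trimming between libraries stays open, although all 3 WT libraries had the 30 bp mode and no GRdim library had it.

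The WT 6pm ChIP-seq list was 2.47 times as long as the 6am list. The WT ChIP-exo list was shorter at 6pm, at 0.821 times the 6am length, from 43.1 against 55.7 M tags. A deeper ChIP-seq library at 6pm would raise the tags per score unit that the score steps imply by over 1.5 times, and the ratio was 1.04. This reading assumes that the score is a tag count divided by the size of the library, which the sources used here do not give. A higher yield of the immunoprecipitation at 6pm stays open; a test of it on the GRdim lists, whose ratio of 2.34 was already known, was written and withdrawn because 1 further pool does not decide it. A biological difference between the times of day stays open too, and 1 pool per condition does not separate them.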
